A study of Micropterus salmoides with 8 samples.

How the data were processed

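Largemouth bass hypothalamus RNA from 4 control and 4 dieldrin-fed males was hybridised to a 2-colour Agilent oligonucleotide array. Groups and replicate numbers came from the sample titles, and dyes from the labels, which give Cy3 for every control and Cy5 for every dieldrin sample. The authors deposited 1 scanner file per sample, made with Agilent Feature Extraction 9.5.1.1, per the file headers. These files hold the mean spot intensity and the median local background intensity of both channels, and processed intensities that the software had background-subtracted and dye-normalized by a linear and lowess method, per the file headers. The deposited files also hold a log10 ratio of red over green processed signals and flags for outlier, saturated and well-measured spots. The log10 ratio was not used for any result. The files of control and dieldrin samples with the same number were byte-identical in 4 of 4 cases, so each pair was taken as 1 array, with the control in green and the dieldrin sample in red. All arrays came from 1 slide and 1 scan by the headers, so no slide term was fitted.

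The authors also deposited a value table of log2 signals in 8 columns, with no statement of its method in the sources used here. Its scale was found by correlating its columns with the log2 processed signals. Its column medians over spots, in column order, were 6.90, 6.90, 6.89, 6.89, 6.89, 6.89, 6.89 and 6.89, so the columns had been brought to nearly 1 median, by a method that stays unknown. Its columns carry signals and not ratios, and their names and contents disagree as described in the results.

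From the mean and background intensities, the background was corrected with normexp and an offset of 50, and log2 ratios were normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and 40 spot values flagged as outliers were left out, and the spots of 1 probe were averaged. The log2 ratio of dieldrin over control of the 4 arrays was tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all 33514 probes and a threshold of 0.05. The ratio within an array makes the array the replicate block. The pairing comes from the shared arrays. After loess and Aquantile normalization the deviations of control and dieldrin samples of 1 array from their group means correlated with r = 0.65, 0.28, 0.33 and 0.35 across probes on arrays 1 to 4. Dye and diet cannot be separated by any fit of these samples. Levels per channel are log2 values after loess and Aquantile and are open to dye bias.

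A probe was taken as well above background on an array where all its spots carried that mark in at least 1 channel. The rule for named probes was fixed before the data were examined. It takes the lowest and highest log2 ratios among probes with an adjusted p under 0.05, the same sign on all 4 arrays and signal well above background on all 4 arrays, 1 probe per gene. Where none pass in a direction it takes those of smallest unadjusted p with 1 sign on all arrays, given as not passed. Because the files pair no probe with a gene, at most 2 identifiers per direction are printed and contigs stood in for genes. The second and the reverse probe of the contig of UF_Msa_AF_106967 were described after their values were seen. The reference table of bass genes held 0 of the contig names among its symbols, tags and accessions.

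The alternatives tried were no background subtraction, the processed signals of the scanner software, median centring without loess, loess followed by Aquantile, a filter on dim probes, array weights, eBayes with a trend and robust prior, a fit with no replicate block, the value table, and leaving out each array in turn. Added after the data were seen were the value table by matched channel, arrays 1 and 3 only, and a fit without probes that share at least 11 bases on the same strand with the known pieces of that contig. The functions were tested on simulated data, 4 arrays with 200 of 33514 probes changed. Of 50 probes each, 70% of those changed by 0.5 on the log2 scale were called in the right direction, 92% of those changed by 1, 98% of those changed by 2 and 100% of those changed by 4, with 6 false calls. These shares do not give the power in the real data. Many planted changes eased the adjusted threshold, whereas the real data gave 12 calls. The simulated noise was also independent between probes and of equal spread on all arrays, unlike the real arrays. Sequence sharing and figures were computed in Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.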

Results

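Gene expression was measured in the hypothalamus of adult male largemouth bass aged 2 to 3 years that had been fed either a diet without pesticide or a diet containing dieldrin for 2 months. Dieldrin is an organochlorine insecticide that blocks GABA-A receptors. Each diet group held 4 fish samples, described in the study design as biological replicates. Total RNA from every control sample carried the green dye Cy3 and total RNA from every dieldrin sample carried the red dye Cy5. The scanner files of control and dieldrin samples with the same number were identical for all 4 numbers, so the 8 samples were taken as 4 control and dieldrin pairs on 4 arrays. All ratios below rest on this pairing and on the dye labels being correct. The column names of the deposited value table give another layout, described further below. By the labels no array had the dyes the other way round, so the ratio of dieldrin to control on these arrays is also the ratio of Cy5 to Cy3.

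The array carried 45220 spots, of which 43803 held 33514 different 60-base probes for bass transcripts. Probes were designed on 15943 assembled transcript contigs, in the forward orientation for 20435 probes and in the reverse orientation for 13079. The files name contigs and do not pair them with genes, so probes are given here by their identifiers. Between 73.4% and 77.5% of the spots were well above background in the control channel and between 75.0% and 76.6% in the dieldrin channel. The median background-subtracted signal per spot ranged from 63.0 to 76.3 intensity units over the control samples and from 84.9 to 121 over the dieldrin samples. No spot was saturated. Duplicate spots of 1 probe differed with an SD of 0.05 to 0.07 in the log2 ratio, and the number of arrays limits the precision.

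The comparison that the design implies is which transcripts differed between dieldrin-fed and control hypothalamus. The largest difference among the probes that passed the test was that of the forward probe UF_Msa_AF_106967. It had a log2 ratio of dieldrin over control of -4.78 ± 0.69 (SD, n = 4 arrays), which is 27.5-fold lower in the dieldrin channel (limma SE 0.26, adjusted p = 0.017). It did not pass without array 3 or without array 4, at limma adjusted p of 0.23 and 0.28, with log2 ratios of -4.64 and -4.72. Its normalised log2 signal was 17.54 ± 0.08 in the control samples and 12.76 ± 0.61 in the dieldrin samples (SD, n = 4 each). By mean signal it ranked 1 of the 33514 probes in the control samples and 1047 in the dieldrin samples. A second forward probe of the same contig had a log2 ratio of -3.24 ± 0.45 (SD, n = 4), or 9.47-fold lower, with a limma adjusted p of 0.016. This second probe ranked 2 in the control samples and 429 in the dieldrin samples. The reverse probe of this contig did not pass the test, with a log2 ratio of -0.51 ± 0.30 (SD, n = 4) and a limma adjusted p of 0.30. Its log2 signal was only 6.92 in the control samples and 6.41 in the dieldrin samples, where it ranked 33412 of the 33514 probes. A fall as large as that of the forward probes could therefore not have shown in it.

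The next largest such difference was that of UF_Msa_CM_133657, a reverse-orientation probe of contig31435. Its log2 ratio was -4.23 ± 0.39 (SD, n = 4), which is 18.7-fold lower in the dieldrin channel (limma SE 0.15, adjusted p = 0.012). Without array 4 it did not pass, at a log2 ratio of -4.22 and a limma adjusted p of 0.19. Its normalised log2 signal was 12.92 ± 0.11 in the control samples and 8.69 ± 0.39 in the dieldrin samples (SD, n = 4 each), and it was well above background in both channels on all 4 arrays. The sequences of these 2 probes were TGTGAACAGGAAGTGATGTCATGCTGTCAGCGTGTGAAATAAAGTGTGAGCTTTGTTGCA for UF_Msa_AF_106967 and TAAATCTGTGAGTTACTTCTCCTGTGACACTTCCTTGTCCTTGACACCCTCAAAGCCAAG for UF_Msa_CM_133657.

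In all, 12 of the 33514 probes passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, and all 12 were lower in the dieldrin channel. They belonged to 10 contigs, and each had a negative log2 ratio on all 4 arrays. Their mean log2 ratios ran from -4.78 to -1.34, so that the smallest of these differences was 2.54-fold. Of the 12 probes, 9 were forward and 3 were reverse. Of the called contigs, 4 had another probe in the same orientation. In 2 of these both probes were called, and in the other 2 the second probe was not well above background and had a log2 ratio between 0.00 and 0.05. The 9 probes that lay on called contigs in the opposite orientation and were well above background had log2 ratios from -0.51 to 0.91, and none of them passed the test. Dim ones among them, such as the reverse probe of the contig of UF_Msa_AF_106967, could not have shown a large fall. Of the 12 called probes, 3 contain the stretch GCTCCGCCTCC, which is also part of the known sequence of the contig of UF_Msa_AF_106967.

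**Figure D1:**
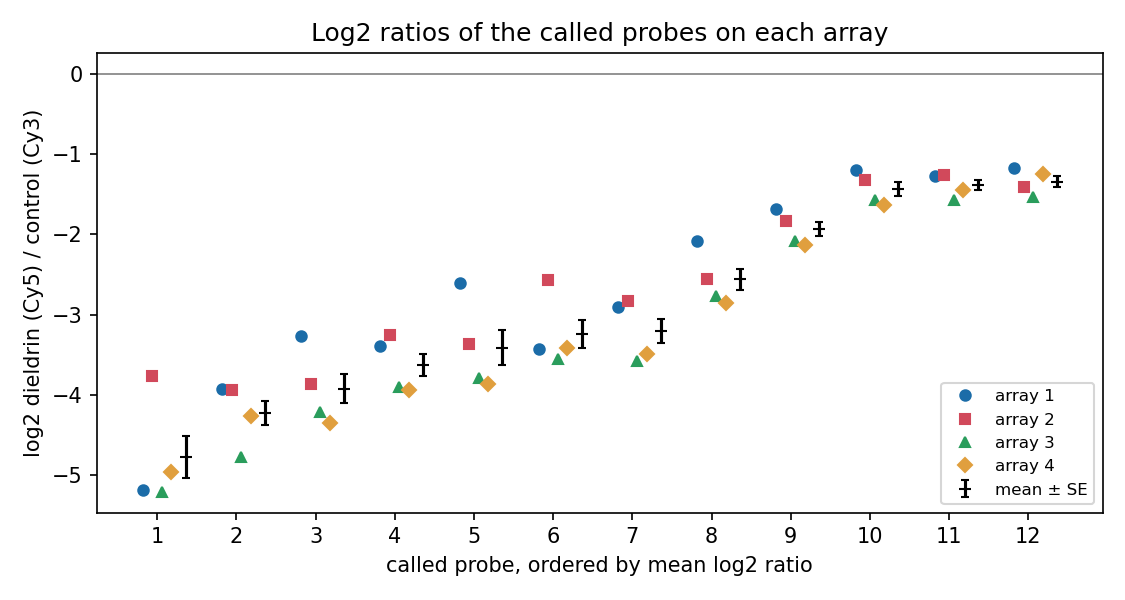
Log2 ratio of dieldrin (Cy5) over control (Cy3) on the y axis for each of the 12 called probes on the x axis, with 1 symbol per array and the mean ± limma SE in black. All values lie below 0, and array 2 stands above the other arrays in probes 1 and 6, which are both on the contig of UF_Msa_AF_106967.

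No probe was called higher in the dieldrin channel by limma after adjustment, although 2865 probes with a higher ratio and 2352 with a lower ratio had an unadjusted p under 0.05, against 1676 in all that chance gives. Their total of 5217 was 2902 without array 2, 2293 without array 4 and 14099 with median centring in place of loess. With the sign of some arrays turned, the highest total of the 7 other arrangements was 1764. Turning signs also raises the spread of each probe whose ratios agree, so these arrangements are no independent reference. The smallest adjusted p of a probe with a higher ratio was 0.11. The 2 higher probes of smallest unadjusted p with 1 sign on all arrays were UF_Msa_CF_122931 and UF_Msa_AF_108487, both forward, neither of which passed. UF_Msa_CF_122931 had a log2 ratio of 0.41 ± 0.03 (SD, n = 4), or 1.33-fold, with a limma adjusted p of 0.11. UF_Msa_AF_108487 had a log2 ratio of 0.48 ± 0.07 (SD, n = 4), or 1.40-fold, with the same adjusted p of 0.11. Both were well above background in both channels on all 4 arrays. Their sequences were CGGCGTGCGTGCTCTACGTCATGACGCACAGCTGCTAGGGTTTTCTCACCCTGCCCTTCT for UF_Msa_CF_122931 and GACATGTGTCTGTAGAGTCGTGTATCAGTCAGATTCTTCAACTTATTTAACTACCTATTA for UF_Msa_AF_108487.

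Most transcripts differed little. Of the 22925 probes well above background in at least 1 channel on every array, 79.0% had a mean log2 ratio within 0.2 of 0. Past 2-fold there were 21 of these probes higher and 33 lower in the dieldrin channel, and past 1.5-fold there were 252 higher and 150 lower. Both counts of lower probes include the 12 called probes. The log2 ratio had the same sign on all 4 arrays for 8040 of them, or 35.1%, against 12.5% for independent signs. Of these 8040 probes, 4783 were higher and 3257 were lower in the dieldrin channel. With median centring, a larger set of 9955 probes had the same sign on all 4 arrays, 7677 higher and 2278 lower. Over all 33514 probes, 55.6% of the ratios were above 0 after loess and 47.1% after median centring. Both methods centre the ratios of each array, which holds this share near an even split, so it does not show a direction of change. Different probes of 1 contig gave similar ratios where they had the same orientation. Among probes well above background, across 3268 contigs with a pair of forward probes that share no 15 bases, the mean log2 ratios correlated with r = 0.85. Across 5971 contigs with a forward and a reverse probe, both well above background, r was 0.23. Both are correlations across contigs, which are not independent replicates. In 79 of the forward pairs the first probe was past 1.5-fold, and the second probe had the same direction in all 79 and was past 1.5-fold in 49.

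The count of calls changed with the arrays used and with the normalization. It was 33 without array 1, 4 without array 2, 1 without array 3 and 0 without array 4, with all of these calls lower in the dieldrin channel. A fit of 3 arrays has fewer degrees of freedom, so these counts do not show that 1 array made the differences. Without array 4 the log2 ratios of UF_Msa_AF_106967 and UF_Msa_CM_133657 were -4.72 and -4.22, against -4.78 and -4.23 with all arrays. When each array was only centred on its median, without loess, limma called 1587 probes higher and 77 lower, so that 95.4% of the calls were higher, against 0% after loess. Without the array pairing, that is, with no replicate block, 27 probes were called, 5 higher and 22 lower.

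The arrays themselves were not alike. The SD of the log2 ratios over probes was 0.15 on array 1, 0.37 on array 2, 0.21 on array 3 and 0.35 on array 4. The mean log2 ratio of the 10 spike-in transcripts, which are added to the samples in set amounts, was 0.25, 1.02, 0.05 and 1.30 on arrays 1 to 4 after loess on the bass probes. The log2 ratios of arrays 2 and 4 correlated with r = 0.60 across probes, against 0.28 to 0.51 for the other pairs of arrays. On arrays 1 and 3 alone, 8 probes were called, all lower, and 5 of them were among the 12.

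**Figure D2:**
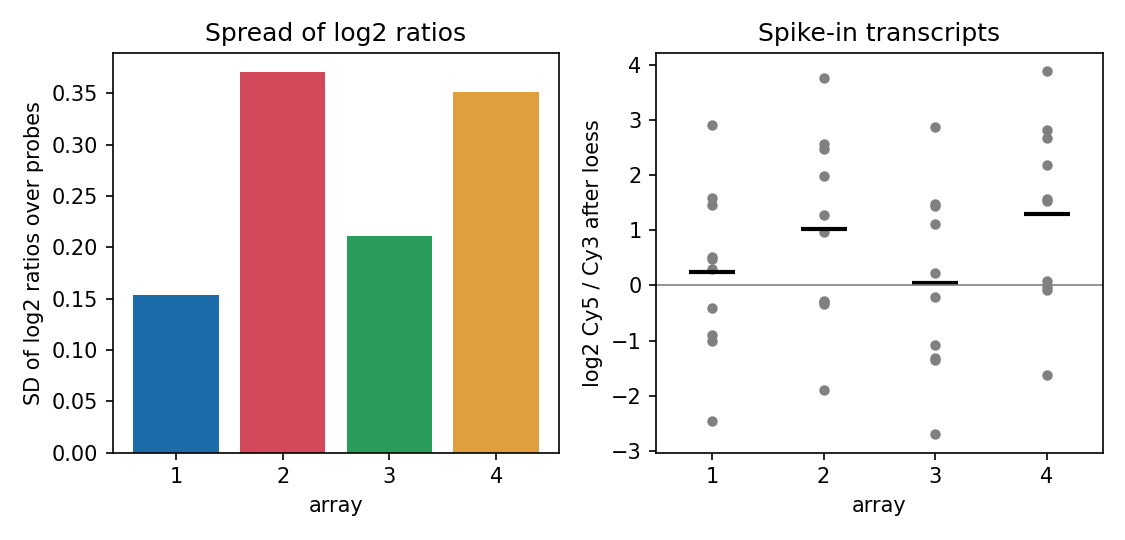
On the left, bars give the SD of the log2 ratios (y axis, log2 units) over probes well above background on each of the 4 arrays. On the right, grey points give the log2 ratio of Cy5 over Cy3 of each of 10 spike-in transcripts and black lines their mean, which is 1.02 on array 2 and 1.30 on array 4.

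The deposited value table of the series holds log2 signals in 8 columns named by sample. Set against the scanner channels, each column matched 1 channel with a correlation of at least 0.9998 across probes, and the next best channel reached at most 0.992. Only 2 of the 8 columns, those of control 1 and dieldrin 4, matched the channel of the sample they are named for, and 4 columns matched a channel of the other dye. The columns named for controls matched both channels of arrays 1 and 2, and the columns named for dieldrin samples matched both channels of arrays 3 and 4. With the columns taken as named, limma called 1 probe, which was higher, and with the columns taken as the channels they matched it called 29, of which 27 were lower.

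**Figure D3:**
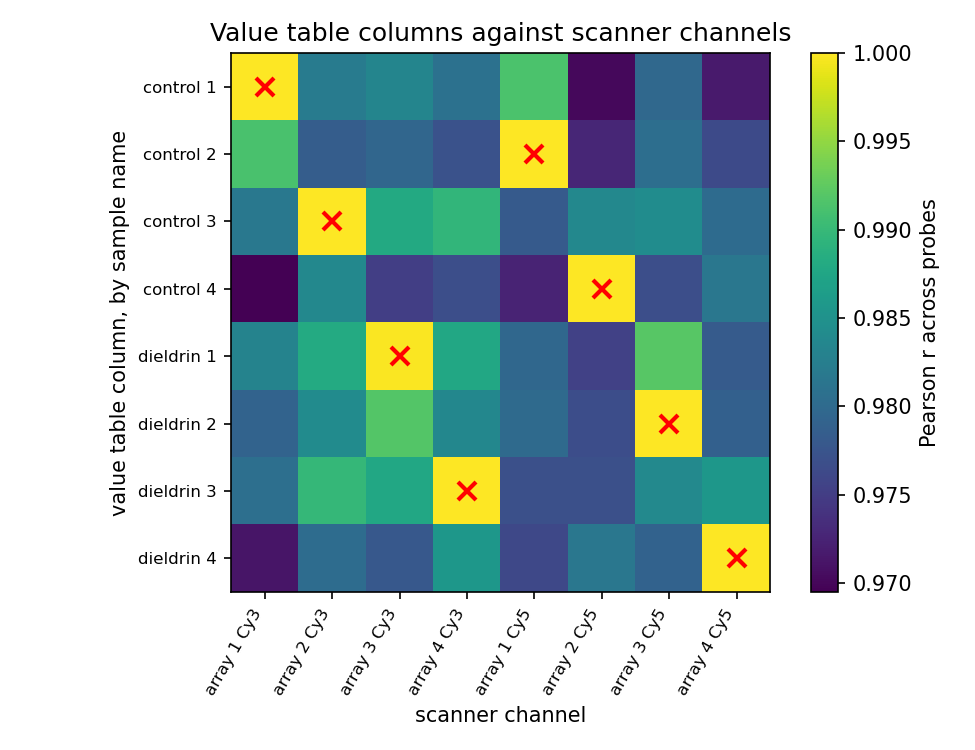
Pearson correlation across probes (colour) between each column of the deposited value table (y axis, by sample name) and the log2 processed signal of each scanner channel (x axis). Red crosses mark the best match of each column, which is the channel of the named sample in 2 of 8 columns.

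The 30 gene lists set before the data were examined, 20 of hypothalamic and dieldrin-related pathways and 10 of markers of other tissues and cell types, could not be scored. No contig name matched a member of any list, so 0 of the 30 lists had a member that could be identified. This does not show that these genes were absent from the array. For the same reason no value is given for GABA-A receptor subunits, gonadotropin-releasing hormones, brain aromatase or estrogen receptors.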

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

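The tests of shared sequence and of dye in this part were chosen only after the calls were seen. Of 19 sets of 4 values compared, 2 held a value far from the other 3, and chance gives about 1 in 20. Both are forward probes of 1 contig, and in both the value of array 2 stands apart. For UF_Msa_AF_106967 the log2 ratio was -3.76 on array 2 and between -5.21 and -4.96 on the others. For the second probe of this contig it was -2.58 on array 2 and between -3.55 and -3.42 on the others.

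All 12 called probes were lower in the dieldrin channel. A candidate explanation for 3 of the 10 calls outside the contig of UF_Msa_AF_106967 is that Cy3-labelled RNA of this contig also bound to them, which the data leave open. Probes sharing at least 11 bases on the same strand with the 3 known pieces of the contig held 3 calls among 161, against 7 among the other 33350 (Fisher's exact test, two-sided p = 1.27e-05), but the length was set after the shared stretch of these 3 had been seen, so this p is no independent evidence. Sharing on the opposite strand gave 0 calls among 153, and with 3 calls that contrast could not have passed, since the smallest p it can give is 0.11. Among uncalled probes, 4 of 158 sharing on the same strand were past 1.5-fold lower in the dieldrin channel, against 132 of 33190 that share on neither strand (Fisher's exact test, two-sided p = 0.0041) and 2 of 153 sharing on the opposite strand (two-sided exact p = 0.68), so these few probes leave open whether the strand matters. The 4 had log2 ratios from -3.18 to -0.90, and the median over all 161 was 0.00. The longest stretches that the 3 called probes share were 11 to 13 bases. Uncalled probes sharing 15 bases on the same strand had log2 ratios of -0.15 and 0.07, and those sharing 14 had from -0.94 to 0.20. The length of the match alone therefore did not set the ratio. All 3 probes that hold GCTCCGCCTCC outside the contig were called. Of those that hold its reverse complement GGAGGCGGAGC, 3 lie on other contigs, with log2 ratios from -0.02 to 0.08, and the reverse probe of the contig itself, which was dim, had -0.51.

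Binding of the same RNA to the other 7 called probes cannot be told apart from changes of their own, because none of the 7 shares 11 bases with the 3 known pieces and the rest of the contig was not analysed here. Dye bias cannot be told apart from an effect of dieldrin for any of the 12 probes, since 0 of the 4 arrays had the dyes swapped. A fall of these transcripts in dieldrin-fed fish stays open and untested. Among the 8 ways to turn the sign of whole arrays, the real one gave 12 calls and the highest of the others gave 0, and only 1 of 8 reached the real count, but 8 splits are too few for a share under 0.05. Turned signs also raise the spread of the called probes, so the other splits are no independent reference.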

How the results depend on the processing

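The value table by matched channel, arrays 1 and 3 only, and the fit without shared sequence were chosen after the data were seen. Against 12 calls, limma gave 59 without background subtraction, 43 with the processed signals, 1664 with median centring, 27 with no replicate block, 1 with the value table as named, 29 with the value table by matched channel and 6 without probes sharing sequence with the contig of UF_Msa_AF_106967. The cause was not tested, except that the last fit took out 5 of the 12 called probes, and its 6 calls were all among the 12. The 12 probes were all among the calls of the first 4 of these and of the table by matched channel, and none was called in the table as named. Leaving out 1 array gave 0 to 33 calls, with 3 arrays in each fit. Within 1.5 times the count were Aquantile with 12, the filter on dim probes with 13, array weights with 12, the trend and robust prior with 13, and arrays 1 and 3 with 8. The pairing by array therefore moved the count from 27 to 12, and each of the 12 was also called with no replicate block.

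The log2 ratio of UF_Msa_AF_106967, -4.78 over all arrays, was -4.64 without array 3 and -4.72 without array 4, where it did not pass with 3 arrays. That of UF_Msa_CM_133657, -4.23 over all arrays, was -4.22 without array 4, where it did not pass either. In the table as named, by contrast, neither passed and the log2 ratios nearly vanished, at -0.27 for UF_Msa_AF_106967 and -0.18 for UF_Msa_CM_133657. There the log2 ratio turned to -0.054 for UF_Msa_CF_122931 and to -0.0083 for UF_Msa_AF_108487. Both of these passed, as higher, with median centring, and UF_Msa_AF_108487 also passed without background subtraction.

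The planned fits of gene lists and of tissue marker lists were not run, because no list had a measured member, and the planned slide term was not run, because there was 1 slide. Probes not well above background, 10589 of 33514, limit what the counts can show.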

Other observations

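In this part the tests of spike-ins, of spot noise, of TG and CA repeats on array 2 alone and of the value table were chosen only after the results were seen, as was the reading of the strand and repeat tests array by array. Probes with 10 or more bases of TG repeat, 26 in all, lay above other probes of the same intensity in the dieldrin channel by 0.13, 0.51, 0.28 and 0.19 log2 units on arrays 1 to 4 (bootstrap SE 0.06, 0.06, 0.07 and 0.04). Reverse-orientation probes lay above forward probes by 0.01, 0.05, 0.04 and 0.06 on the same arrays. With dye and diet on the same samples, these values belong to either.

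The wider log2 ratios of arrays 2 and 4 went with higher spike-in ratios. Spot-to-spot noise does not account for them. Over 8596 probes with duplicate spots and well above background, the variance between duplicate spots was 0.0027, 0.0042, 0.0037 and 0.0038 on arrays 1 to 4. It made at most 1.1% of the excess variance of array 2 or 4 over array 1 or 3. An even rise of signal from the reverse strand is argued against as well. The lower excess of arrays 2 and 4 exceeded the higher of arrays 1 and 3 by 0.0081 (bootstrap SE 0.0046), under the 0.05 set for it. The mean excess of arrays 2 and 4 lay 0.030 (bootstrap SE 0.0036) above that of arrays 1 and 3, also under 0.05. These SEs resample probes and do not measure variation between arrays. The spread of reverse and forward probes was not compared, so an uneven rise was not tested. For TG repeats the lower of arrays 2 and 4 minus the higher of arrays 1 and 3 was -0.085 (bootstrap SE 0.077). This argues against them as a shared cause, since array 4 lay below array 3. Array 2 lay 0.23 above the higher of arrays 1 and 3 and brought the difference of the means to 0.14. Only 26 of the 22925 probes well above background hold such repeats, while 573 were past 2-fold on array 2, against 50 and 104 on arrays 1 and 3. The TG-repeat probes are thus too few to account for the wider ratios of array 2. The 17 probes with CA repeats lay only 0.027 (bootstrap SE 0.055) higher on array 2, which leaves a shift undecided, and they too are too few to widen the ratios. Less labelled fish RNA per spike-in in the dieldrin channel is a possible explanation, because the spike-in mean was at least 0.78 log2 units higher on arrays 2 and 4, with all 10 spike-ins higher. This ratio cannot tell less labelled fish RNA in the dieldrin channel from more in the control channel. How either would widen the ratios, and whether the fish on those arrays differed, was not tested. The median background-subtracted signal of the dieldrin channel was 113, 84.9, 99.2 and 121 on arrays 1 to 4, so it was lower on array 2 but not on array 4. That of the control channel was 63.0, 76.3, 63.2 and 71.1, so it was higher on arrays 2 and 4.

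The same sign on all arrays was seen for 8040 probes in the real arrangement and for at most 3727 in the others, so 1 of 8 reached the real count, and 8 are too few for a share under 0.05. A probe can have 1 sign on all arrays in only 1 of the 8 arrangements. A high real count therefore lowers the others, which are no independent reference. In the fit without array pairing, 2 of the 35 splits of the 8 samples gave at least the real 27 calls, so chance could not be excluded there. The highest other split gave 618 and set both samples of arrays 1 and 3 against both of arrays 2 and 4, which points to a structure of the samples by array. Among the 8 splits that part every array, as the real one does, the highest other count was 0. These other splits put a consistent difference into the spread, so they are no independent reference.

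For the mismatch between value table columns and sample names, 2 candidate explanations were compared, scanner files attached to the wrong samples and columns deposited in array order. If the scanner files had been attached to the wrong samples, every column would hold the dye its label gives, and 4 of the 8 columns held the other dye. This comparison takes the dye labels as correct, so it cannot decide a case in which the labels are wrong too. If the columns were deposited in array order, Cy3 then Cy5 for each array in turn, all 8 would match that order, and 8 of 8 did. No biological explanation was tested for this pattern. By the sample names, the table sets arrays 1 and 2 against arrays 3 and 4, with both diets on each side if the dye labels are correct.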
